A study of Mus musculus with 12 samples.

How the data were processed

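Total RNA of 12 explant samples was profiled on Affymetrix Clariom S mouse arrays, whose identity was read from the probe set names and the platform annotation used here. Per the labels' protocols, RNA was isolated in culture with a kit for total RNA, and sense-strand cDNA was made from 10 ng and labelled with a kit for small inputs. The deposited value table holds 1 column per sample with 28815 probe sets. Its values run from 1.50 to 13.65 and were read as log2 expression values from that range. The authors' normalization, summarisation, centring and log base are not given in the sources used here, so the log2 scale of these deposited values is an inference, and each difference would scale with another base. The median over all probe sets lay between 6.32 and 6.43 in the 12 arrays, so their overall levels were alike. The medians of the negative controls were less so, from 4.69 to 5.20.

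A second deposited table was not used, because the names of its 12 value columns match no sample label. Groups and replicate numbers were taken from the sample titles: PGC-1alpha or control-line explants, in water or in phenformin, 3 samples each. Of the 28815 probe sets, 22206 are mouse transcript clusters, 5222 negative controls, 1324 positive controls and 63 spike-in controls. Gene symbols came from the platform annotation, updated through Entrez identifiers against a RefSeq table of GRCm38.p6, where all 19572 named probe sets matched and 0 symbols changed. Those 19572 probe sets carry exactly 1 symbol, 0 carry several, and 2634 transcript clusters are unnamed here and were not analysed here. For the 55 genes with several probe sets the 1 with the highest mean over the 12 arrays was kept, which left 19505 genes. Control probe sets were left out of the tests, and no filter on level was applied. Coordinates are not given because no genome build is named for the array values.

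Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as 4 group means over the 12 arrays, without a replicate block. The fit had 8 residual degrees of freedom and a prior of 5.84. The contrasts were PGC-1alpha minus control-line in each treatment, phenformin minus water in each line, and the difference between the phenformin responses. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested within a contrast and a threshold of 0.05. Agreement between contrasts that share no arrays was measured by Pearson's r across genes and by the overlap of calls per direction, set against the product of the list sizes divided by the number of genes. Both lists used the same estimate of each gene's spread, which favours shared calls, so this reference for independent lists is low.

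Gene lists fixed before the data were examined covered respiratory chain complexes, mitochondrial and cytosolic ribosomes, metabolic pathways, stress, immune and proliferation programs, ErbB signalling output, epithelial and mesenchymal genes and markers of other cell types. Of these, 36 had measured members. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry, which tests whether a list moves one way. Of the lists, 13 passed camera in no contrast: the PGC-1 family, complexes II and III, the tricarboxylic acid cycle, mitochondrial import, mitochondrial antioxidants, the pentose phosphate pathway, serine and one-carbon metabolism, ErbB output, epithelial genes, and leukocyte, endothelial and lung epithelial markers. Their smallest adjusted p was 0.0865 and their medians lay between -0.21 and 0.18. Transcripts of the mitochondrial genome and some list members were not analysed here.

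Named genes were chosen by a rule fixed before the data were examined. Ppargc1a came first. Then came, per contrast, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 3 arrays of 1 group all lay above the other 3, leaving out predicted, olfactory, vomeronasal and small RNA gene symbols. Up to 4 members per list and contrast with the smallest adjusted p were added, and for the difference of responses the 5 genes with the smallest p. The files hold no detection calls, so the 95th percentile of the negative control probe sets of each array served as background. Where no array of the dimmer group exceeded it, the fold is given as at least the bright group's mean over the dim group's mean of the higher of that percentile and the probe set's own value. Between 34.6% and 39.1% of genes exceeded it per array. Negative control probe sets carry signal of their own, so this limit is strict.

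The fits were tested on simulated data with the real genes' means and spreads and 200 changed genes. The simulated noise was independent between genes and had the same spread in all groups. The shares below therefore do not cover noise that genes of an array share or a spread that differs between groups. In the comparison of phenformin with water in control-line explants, 34% of genes changed by 0.5 (log2) were recovered, 90% of those changed by 1 and 100% of those changed by 2 or 3, over 19505 genes. For the difference of responses the shares were 8%, 42%, 98% and 100%. The share of false calls among all simulated calls was 3%, 4% and 4.6% for the first 3 comparisons, 5.3% for the difference and 9.2% (16 of 174) for PGC-1alpha in phenformin, above the 5% aimed at. Alternatives tried were limma's trended and robust prior, fitting only the groups compared, array weights, renewed quantile normalization, median centring, a filter on dim genes, averaging probe sets, a replicate block, and leaving out each replicate. A fit with the gap between positive and negative controls as a covariate, average effects over both lines or treatments, and exact permutation tests of per-array list scores were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.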

Results

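Lung metastases that had formed in mice after tail vein injection of NMuMG-ErbB2 cells were taken into culture as explants, and their total RNA was measured on expression arrays. NMuMG is a mouse mammary gland epithelial line, here carrying the ErbB2 oncogene. The injected cells either overexpressed PGC-1alpha, the transcriptional coactivator encoded by Ppargc1a that is known for driving mitochondrial biogenesis, or were control cells. Explants of each line were treated for 4 days with 100 uM phenformin, a biguanide that inhibits complex I of the respiratory chain, or with water. The 12 arrays fell into 4 groups of 3, and 19505 genes were tested. Values are on a log2 scale, errors of differences are standard errors from limma, and n = 3 per group throughout. The number of arrays limits the precision, and because the labels do not say whether replicates came from separate animals or cultures, p-values measure the spread between these samples, which may be technical. Comparisons of the lines cannot tell an effect of PGC-1alpha from any other difference between the explanted metastases of both lines.

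Ppargc1a itself followed the labels in all 12 arrays. Its log2 value was 8.14 ± 0.11 (SD, n = 3) in PGC-1alpha explants in water and 8.25 ± 0.10 (SD, n = 3) in phenformin. In control-line explants it was 7.11 ± 0.09 (SD, n = 3) in water and 7.12 ± 0.16 (SD, n = 3) in phenformin. The lowest PGC-1alpha array stood at 8.06 and the highest control-line array at 7.29. The difference was 1.03 ± 0.12 in water (adjusted p = 0.000201) and 1.13 ± 0.12 in phenformin (adjusted p = 5.9e-05). No control-line array exceeded the 95th percentile of its own negative control probe sets, so the folds are bounds: at least 1.29-fold in water and at least 1.26-fold in phenformin. The same kind of bound is given below wherever a gene exceeded that percentile in 1 group only, and no fold is given where it did so in neither group.

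The first comparison asked what differed between PGC-1alpha and control-line explants kept in water. Sod3, the extracellular superoxide dismutase, was 6.49-fold lower in PGC-1alpha explants (log2 difference -2.70 ± 0.23, adjusted p = 2.45e-05), and the water channel Aqp5 was 5.68-fold lower (-2.51 ± 0.21, adjusted p = 2.31e-05). Ifitm3, an interferon-induced membrane protein that restricts viral entry, was 4.88-fold lower, and the endocytic adaptor Dab2 was 4.28-fold lower. Grem1, a secreted BMP antagonist, was at least 4.40-fold lower (-2.69 ± 0.16), the myelin protein Pmp22 at least 2.22-fold (-2.90 ± 0.23), and the phosphatase Ptpn7 and the lysyl oxidase Loxl3 at least 1.81-fold each. Mxra8 (-2.24 ± 0.13) and Adgrg2 (-2.27 ± 0.22) were also lower, with both groups inside the range of the negative controls. Among genes that were higher in PGC-1alpha explants, Ugt2b34, a glucuronosyltransferase, was 2.52-fold higher, the mannose receptor Mrc1 2.42-fold higher, and P-selectin, Selp, was higher by 1.32 ± 0.28. The ion channel Trpa1 was at least 1.51-fold higher, the milk protein kappa-casein, Csn3, at least 1.32-fold, the ephrin receptor Epha5 at least 1.14-fold and Pate14 at least 1.02-fold (log2 difference 2.43 ± 0.23). Armcx3 (2.24 ± 0.23), Tlcd4 (1.77 ± 0.17) and Chst15 (1.33 ± 0.13) were higher within the range of the negative controls.

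Among the gene lists fixed before the data were examined, those of complex I, complex IV and the cytosolic and mitochondrial ribosomes shifted up in PGC-1alpha explants in water, by small amounts and without single genes passing upwards. The median log2 difference was 0.18 over 36 complex I subunits (camera adjusted p = 0.000364) and 0.15 over 16 complex IV subunits with cytochrome c (adjusted p = 0.0114). It was 0.13 over 62 cytosolic ribosomal proteins (adjusted p = 8.47e-08) and 0.14 over 76 mitochondrial ribosomal proteins (adjusted p = 2.9e-05), of which Mrpl39 was lower (-0.47 ± 0.10). Adjusted over the list alone, 1 complex I subunit rose and no cytosolic ribosomal protein passed. Ndufa1 had the smallest adjusted p of the complex I subunits (0.55 ± 0.13, adjusted p = 0.0507). With an estimated correlation the adjusted p was 0.371 for complex I and 0.312 for each of the other 3 lists, and with fry it was 0.0684 for complex I and 0.0501 for mitochondrial ribosomal proteins. The lists of complex II (median -0.03, adjusted p = 0.946), complex III (0.18, 0.0865) and ATP synthase (0.13, 0.114) did not pass. Lists of the tricarboxylic acid cycle (median 0.07, adjusted p = 0.365) and of fatty acid oxidation (median -0.05, adjusted p = 0.284) did not pass. Of 15 PGC-1 family members and partner factors, Ppargc1a was the only 1 past the threshold, and the list did not pass (median 0.04, adjusted p = 0.573).

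The glycolysis, mesenchymal and antigen presentation lists shifted down in PGC-1alpha explants in water, with few single genes past the threshold. Of 23 glycolysis genes, 3 were lower: Slc2a1, the glucose transporter GLUT1, by 1.72-fold (-0.79 ± 0.15), and the phosphofructokinases Pfkm (-0.62 ± 0.11) and Pfkp (-0.61 ± 0.12). The list's median was -0.11 (camera adjusted p = 0.00595), and the same 3 passed when adjusted over the list alone. Of 21 mesenchymal transition genes, Sparc was lower (1.49-fold, -0.58 ± 0.10), 4 were lower when adjusted over the list alone, and the median was -0.16 (adjusted p = 0.000364). The class I genes H2-K1 (1.67-fold, -0.74 ± 0.13) and H2-D1 (at least 1.30-fold, -0.61 ± 0.12) were lower among 16 antigen presentation genes, with a median of -0.20 (adjusted p = 0.000364). Of 25 interferon response genes none passed over all genes, and adjusted over the list alone 4 were lower and 1 higher, with a median of -0.16 (adjusted p = 0.00711). Of 20 hypoxia targets, Egln3 (1.66-fold, -0.73 ± 0.12) and Stc1 (-0.90 ± 0.18) were lower, with a median of -0.09 (adjusted p = 0.035). With an estimated correlation the adjusted p was 0.0778 for the mesenchymal list, 0.179 for glycolysis, antigen presentation and interferon, and 0.441 for hypoxia, which fry did not call either (adjusted p = 0.109). Markers of other cells that an explant could hold did not shift together: the median was -0.10 for fibroblast and mural cells, -0.01 for macrophages and leukocytes, -0.01 for endothelial cells and -0.10 for lung epithelium, with adjusted p from 0.573 to 0.823. Most of these markers lay within the range of the negative controls: under phenformin, 4 of 52 fibroblast, leukocyte and endothelial genes exceeded it in all arrays of a group. Mrc1, at its place in the leukocyte list, was higher while the endothelial marker Flt1 was lower (-0.56 ± 0.12).

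In all, limma called 391 of 19505 genes at an adjusted p under 0.05, with 124 higher and 267 lower in PGC-1alpha explants, or 31.7% higher, against 44.7% without control-line water replicate 3. Without replicate 1 of the PGC-1alpha water group the count was 247, and the glycolysis (adjusted p = 0.0518), interferon (0.0533), complex IV (0.144) and hypoxia lists no longer passed. The hypoxia list was also lost without PGC-1alpha water replicate 3 or control-line water replicate 3, with an adjusted p of up to 0.235, and the interferon and hypoxia lists were lost above the median level. Of 40 named genes past the threshold, 26 passed whichever array was left out.

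**Figure D1:**
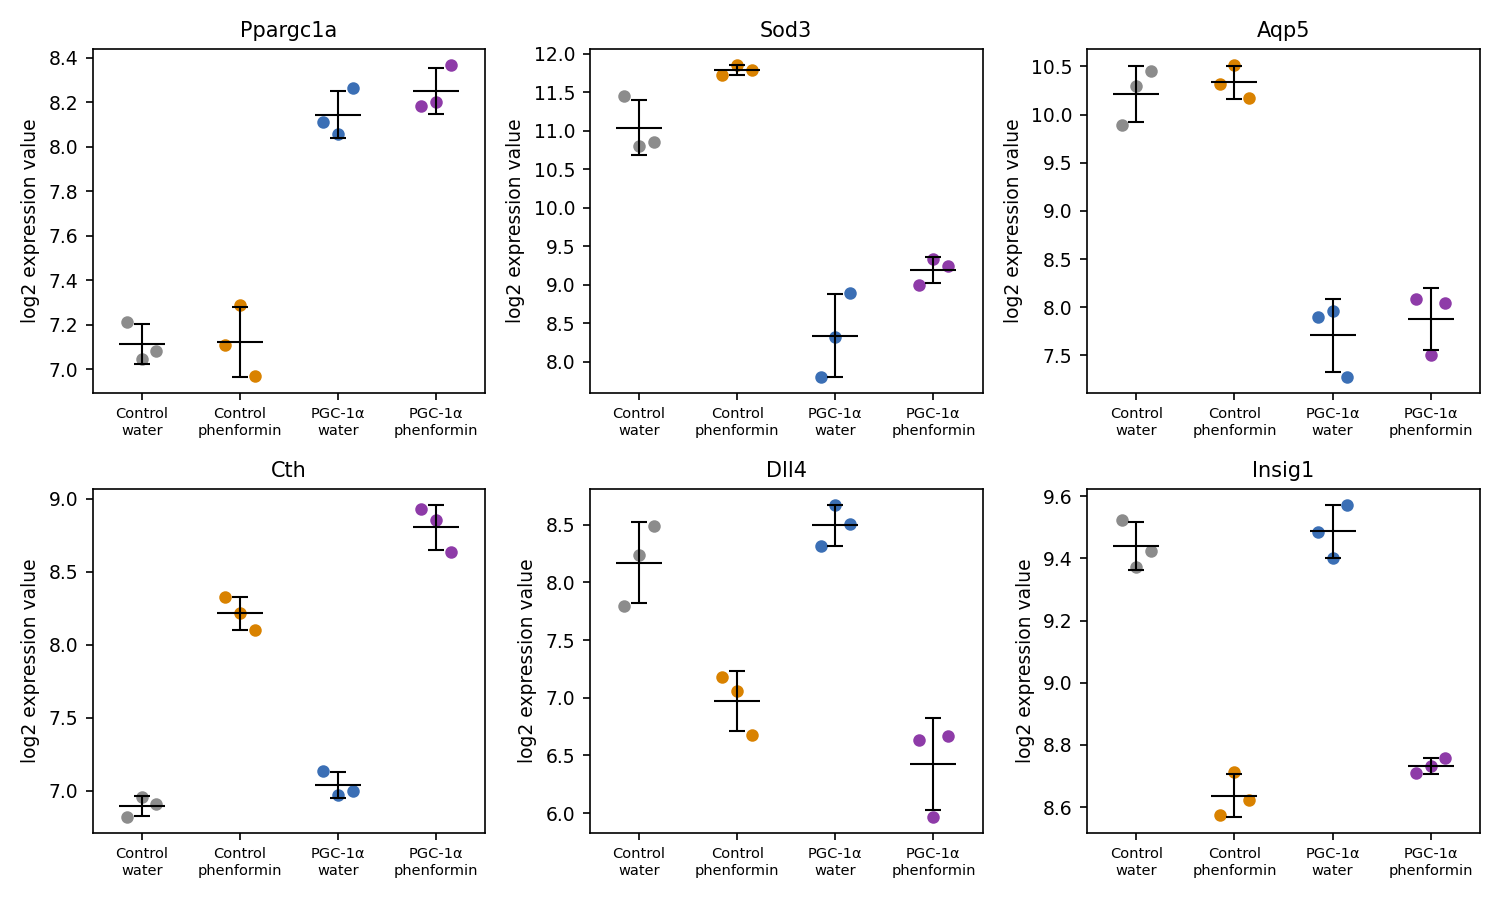
Log2 expression value (vertical axis) of 6 named genes in each of the 12 arrays, by group (horizontal axis), with 1 point per array and a bar at the group mean with its SD (n = 3). Sod3 and Aqp5 were lower in the PGC-1alpha arrays of both treatments, Cth was higher and Dll4 and Insig1 were lower in the phenformin arrays of both lines, and Ppargc1a stood at 8.06 or above in PGC-1alpha arrays.

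The second comparison asked what phenformin changed in control-line explants. The cholesterol synthesis list shifted down. Of 19 measured members, 6 fell, none rose and 13 did not pass. Adjusted over the list alone, 14 fell. The mevalonate pathway isomerase Idi1 fell 1.92-fold (-0.94 ± 0.18), the lanosterol demethylase Cyp51 1.84-fold (-0.88 ± 0.13), Insig1, an endoplasmic reticulum protein that restrains sterol synthesis, 1.74-fold (-0.80 ± 0.10) and lanosterol synthase, Lss, 1.59-fold (-0.67 ± 0.10). The list's median was -0.37 (camera adjusted p = 5.24e-13, and adjusted p = 0.22 with an estimated correlation). The list of targets of ATF4, the transcription factor of the integrated stress response, shifted up: of 29 measured, 3 rose and none fell, 10 rose and 1 fell when adjusted over the list alone, and the median was 0.26 (adjusted p = 8.42e-06, and adjusted p = 0.356 with an estimated correlation). The 3 were Cth, the cystathionine gamma-lyase that makes cysteine (at least 1.35-fold, 1.32 ± 0.11, adjusted p = 0.000268), Vldlr (1.64-fold) and Chac1, a glutathione-degrading enzyme (1.65-fold).

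The NRF2 and unfolded protein response lists shifted up as well, with few single genes past the threshold. Of 19 NRF2 antioxidant targets, 3 rose: the glutathione transferases Gstm1 (2.49-fold, 1.32 ± 0.29) and Gsta4 (1.76-fold, 0.81 ± 0.14), and Cbr1 (0.81 ± 0.15) within the range of the negative controls. Adjusted over the list alone 8 rose, and the median was 0.24 (camera adjusted p = 0.000123, and adjusted p = 0.356 with an estimated correlation). Of 18 genes of the unfolded protein response, Sdf2l1 rose (1.47-fold), 5 rose when adjusted over the list alone, and the median was 0.22 (adjusted p = 4.32e-05, and adjusted p = 0.386 with an estimated correlation). Among 29 NF-kB targets and chemokines, Cxcl5 (1.71-fold, 0.78 ± 0.11), Ccl7 (1.49-fold) and Lcn2 (0.84 ± 0.18, within the range of the negative controls) rose, and the median was 0.14 (adjusted p = 0.0499, and adjusted p = 0.445 with an estimated correlation). Single members rose in the lists of tRNA synthetases (Wars, 1.54-fold, median 0.15, adjusted p = 0.00631), p53 targets (Btg2, at least 1.05-fold, median 0.15, adjusted p = 0.013) and interferon response (Bst2, 1.81-fold, median 0.17, adjusted p = 0.0499). With an estimated correlation those 3 lists had an adjusted p of 0.39, 0.39 and 0.386.

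Outside the lists, the largest rises in control-line explants were those of the adhesion receptor Adgrg2 (at least 2.42-fold, 1.72 ± 0.22), Selp (3.01-fold, 1.59 ± 0.28), the cytochrome P450 Cyp1b1 (2.76-fold, 1.47 ± 0.19), the phospholipid transfer protein Pltp (2.32-fold) and the mitochondrial protein Chchd10 (2.32-fold). Clic3 (1.24 ± 0.17), Pkhd1l1 (1.22 ± 0.19) and Gstm7 (1.18 ± 0.13) rose without a fold that could be bounded. The Notch ligand Dll4 fell at least 1.19-fold (-1.20 ± 0.21), Txnip, an inhibitor of glucose uptake whose expression follows glucose metabolites, fell 1.95-fold (-0.97 ± 0.16), and the nuclear matrix protein Safb fell 1.85-fold. Pate14 (-1.13 ± 0.23), the hyaluronan synthase Has2 (-1.08 ± 0.17), Cenpw (-0.78 ± 0.16) and P4ha3 (-0.77 ± 0.15) fell within the range of the negative controls. The keratin gene Krt19 rose 1.62-fold and the phosphofructokinase Pfkp 1.54-fold.

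The complex I and ATP synthase lists shifted slightly in control-line explants under phenformin, with no single gene past the threshold over all genes, and complexes II, III and IV did not pass (adjusted p of 0.575, 0.238 and 0.319). The median was 0.13 over complex I subunits (camera adjusted p = 0.00393), 0.08 over ATP synthase subunits (adjusted p = 0.0449) and 0.06 over 27 fatty acid oxidation genes (adjusted p = 0.0499). The lysosome list (median 0.13, adjusted p = 0.0449), mitotic genes (0.11, 0.0499), fatty acid synthesis (-0.09, 0.0499) and fibroblast and mural cell markers (-0.13, 0.0499) stood near the threshold. The adjusted p with an estimated correlation lay between 0.356 and 0.647 for these 7 lists. Endothelial (median -0.12), leukocyte (0.04) and lung epithelial markers (-0.03) did not pass.

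limma called 234 genes in control-line explants, with 179 higher and 55 lower in phenformin, or 76.5% higher, against 66.1% after the values were quantile normalized again. The count was 40 without control-line water replicate 2, 601 without control-line water replicate 3 (339 higher and 262 lower, or 56.4% higher), and 96, 21 and 46 without control-line phenformin replicates 1, 2 and 3. Negative control probe sets were brighter in all 6 phenformin arrays than in all 6 water arrays, with medians of 5.09 to 5.20 against 4.69 to 5.02, and with the gap between positive and negative controls as a covariate, chosen after seeing the data, limma called no gene, with 1642 at an unadjusted p under 0.05. Of 34 named genes past the threshold, 8 passed whichever array was left out: Adgrg2, Clic3, Cth, Cxcl5, Cyp1b1, Cyp51, Gstm7 and Insig1. The cholesterol, ATF4, NRF2 and unfolded protein response lists also passed in each of those 6 fits, and the other 11 did not, with adjusted p of up to 0.533. Without water replicate 2 none of these 11 passed. That array stood apart on the second principal component, at 33.3 against 9.2 for the next highest array. It also had the highest score of the 12 arrays for fibroblast (0.227), leukocyte (0.135), endothelial (0.151) and lung epithelial markers (0.255). The fatty acid oxidation list was lost without any 1 of the 6 arrays. Without water replicate 1, the ATP synthase, lysosome, mitotic and interferon lists were lost, and without water replicate 3, the fatty acid synthesis, fibroblast, interferon and NF-kB lists. Without phenformin replicate 1 the ATP synthase, lysosome, mitotic, interferon, fatty acid synthesis and fibroblast lists were lost. Without phenformin replicate 2 the same held for the ATP synthase, lysosome, mitotic, interferon, fibroblast, NF-kB and p53 lists, and without replicate 3 for the fatty acid synthesis, fibroblast and NF-kB lists. With fry the complex I, NF-kB, interferon, mitotic and fibroblast lists were lost (adjusted p from 0.0537 to 0.229). After quantile normalization the complex I, ATP synthase, fatty acid oxidation, tRNA synthetase, p53, NF-kB, lysosome, fibroblast and mitotic lists were lost, and above the median level these and the interferon list.

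The third comparison asked the same of PGC-1alpha explants. Cth rose at least 1.97-fold (1.77 ± 0.11, adjusted p = 6.17e-06), the smallest adjusted p of the comparison. The corneodesmosome protein Cdsn rose at least 1.76-fold (1.10 ± 0.14), Reep6, which shapes the endoplasmic reticulum, 1.97-fold, the growth factor Bmp4 1.94-fold, the mucin-type glycosyltransferase Gcnt3 1.90-fold and the oxysterol hydroxylase Cyp39a1 1.84-fold. Car6 (1.07 ± 0.18), Sh2d4a (0.97 ± 0.14), Slc44a3 (0.94 ± 0.16) and Zbtb7c (0.87 ± 0.14) rose within the range of the negative controls. Dll4 fell at least 1.46-fold (-2.07 ± 0.21, adjusted p = 0.000866), Txnip fell by 1.60 ± 0.16 (adjusted p = 0.000866), and the Notch ligand Jag1 fell 1.78-fold (-0.83 ± 0.14). Fibronectin, Fn1, fell 2.08-fold (-1.06 ± 0.15), the intermediate filament gene Nes 1.69-fold, Ccbe1, a matrix protein of lymphatic growth, 1.85-fold, Mcpt8 1.59-fold, and urokinase, Plau, fell by 0.75 ± 0.14 on the log2 scale.

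The cholesterol synthesis list shifted down in PGC-1alpha explants too. Cyp51 (1.81-fold, -0.86 ± 0.13) and Insig1 (1.69-fold, -0.75 ± 0.10) passed over all genes, 17 did not, and 15 fell when adjusted over the list alone. The median was -0.43 (camera adjusted p = 1.83e-16, and adjusted p = 0.115 with an estimated correlation). Of the ATF4 targets, Cth and Vldlr (1.56-fold) rose, 8 rose and 1 fell when adjusted over the list alone, and the median was 0.21 (adjusted p = 1.43e-07, and adjusted p = 0.388 with an estimated correlation). In 24 DNA replication genes the median was -0.21 (adjusted p = 3.35e-05), with none past the threshold over all genes and 2 lower when adjusted over the list alone. The values of Fen1 (-0.59 ± 0.16) and Gins2 (-0.37 ± 0.10) had the smallest adjusted p of that list, 0.186 and 0.172. The tRNA synthetases had a median of 0.09 (adjusted p = 0.0265) and the fatty acid synthesis genes of -0.17 (adjusted p = 0.0437), with no gene past the threshold. The adjusted p with an estimated correlation was 0.653 for each of these last 3 lists, and with fry it was 0.203 for DNA replication and 0.225 for tRNA synthetases. Complex I subunits had a median of 0.01 (adjusted p = 0.852), and no list of markers of other cell types passed.

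limma called 38 genes, with 26 higher and 12 lower in phenformin, or 68.4% higher. The count was 14, 12 and 77 without PGC-1alpha water replicates 1, 2 and 3, and 3, 5 and 11 without PGC-1alpha phenformin replicates 1, 2 and 3, and the share of higher calls in those fits lay between 33.3% and 79.2%. Cth, Dll4 and Txnip passed in each of those 6 fits, the only 3 of 22 named genes past the threshold to do so, and without phenformin replicate 2 the others were Ccbe1 and Cdsn. The tRNA synthetase list was lost without replicates 1 or 3 of either group and the fatty acid synthesis list without water replicates 2 or 3 or phenformin replicates 1 or 3, with adjusted p of up to 0.0955 and 0.167, and the tRNA synthetase list was lost above the median level. The negative controls were brighter by 0.17 in phenformin arrays of this line, and with the control gap as a covariate 1 gene passed, Cth (1.63 ± 0.18).

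The phenformin responses of both lines, which share no arrays, were then set side by side. Across the 19505 genes the differences correlated with r = 0.46, where genes are not independent replicates. The genes called in both lines numbered 20 upwards, against 0.239 for independent lists, and 6 downwards, against 0.034, and none was called in opposite directions. The negative controls rose in both lines too (by 0.29 in control-line and 0.17 in PGC-1alpha explants), so a technical shift shared by both lines is not excluded. Downwards these were Dll4, Txnip, Cyp51, Insig1, Jag1 and Ccbe1. Upwards they included Cth, Cdsn, Car6, Gcnt3, Reep6, Sh2d4a, Pfkp and Vldlr. All 38 genes called in PGC-1alpha explants had the same sign in control-line explants, and 214 of the 234 called in control-line explants had the same sign in PGC-1alpha explants. Over all genes tested the share with the same sign was 63.1%.

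The test of the difference between those responses called no gene. limma gave 1018 genes at an unadjusted p under 0.05, where chance gives 975, and the smallest adjusted p was 0.164. The 5 genes with the smallest p are given as values of the PGC-1alpha response minus the control-line response. They were -1.74 ± 0.27 for the steroid dehydrogenase Akr1c18, -1.19 ± 0.19 for Mal, -1.52 ± 0.25 for Clic3, 1.00 ± 0.17 for Adamts15 and 0.96 ± 0.17 for the transporter Slc6a13, with adjusted p from 0.164 to 0.228. With limma's trended and robust prior Akr1c18, Mal and Clic3 passed, and without PGC-1alpha phenformin replicate 1 Clic3 passed. The counts of 234 and 38 genes are therefore not shown to differ by this test. Of the lists, 4 passed with smaller or more negative responses in PGC-1alpha explants: DNA replication (median -0.17, camera adjusted p = 0.00551), the unfolded protein response (-0.14, 0.00992), NF-kB targets (-0.19, 0.0246) and complex I (-0.11, 0.0301). No member passed over all genes, and with an estimated correlation the adjusted p was 0.70 for each. None of the 4 passed with fry (adjusted p from 0.333 to 0.343) or above the median level, and of the 4 only NF-kB passed after quantile normalization. None passed without PGC-1alpha water replicate 3 or without control-line water replicate 2. The latter array had the highest marker scores of other cells and the lowest medians of the positive and negative controls. DNA replication and NF-kB were also lost without PGC-1alpha phenformin replicate 1, the unfolded protein response without control-line phenformin replicate 1, and NF-kB without control-line water replicate 3 or control-line phenformin replicate 3, with adjusted p of up to 0.27. Complex I was also lost without PGC-1alpha water replicate 2, PGC-1alpha phenformin replicate 2, control-line water replicate 1 or control-line phenformin replicate 1, with an adjusted p of up to 0.473.

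The last comparison asked what differed between PGC-1alpha and control-line explants under phenformin. The interferon and mesenchymal lists shifted down in PGC-1alpha explants. Of 25 interferon response genes 6 were lower, none higher, and 10 were lower when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 4.88e-05, and adjusted p = 0.0423 with an estimated correlation). They included Xaf1 (-0.97 ± 0.19), the RNA sensor Ddx58 (-0.90 ± 0.16), Gbp2 (-0.60 ± 0.14) and Isg15 (-0.59 ± 0.14), all 4 within the range of the negative controls. Restricted to genes above the median level, the list no longer passed (adjusted p = 0.464, against at most 0.000532 with an array left out), and 2 of its 25 members exceeded the negative controls in all arrays of a group. Of 21 mesenchymal transition genes 5 were lower and 8 when adjusted over the list alone, among them Fn1 (1.77-fold, -0.82 ± 0.15), Sparc (1.68-fold, -0.75 ± 0.10), the repressor Snai1 (at least 1.68-fold, -0.78 ± 0.15) and Snai2 (1.56-fold, -0.64 ± 0.13). The median was -0.21 (adjusted p = 0.000364, and adjusted p = 0.0423 with an estimated correlation). Of the genes named in this paragraph, Gbp2 and Isg15 passed in 2 of the 6 fits with an array left out, Snai2 in 3 and Xaf1 in 5. Ddx58, Fn1, Sparc and Snai1 passed in all 6. The median of 25 epithelial genes was 0.02 (adjusted p = 0.886).

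**Figure D2:**
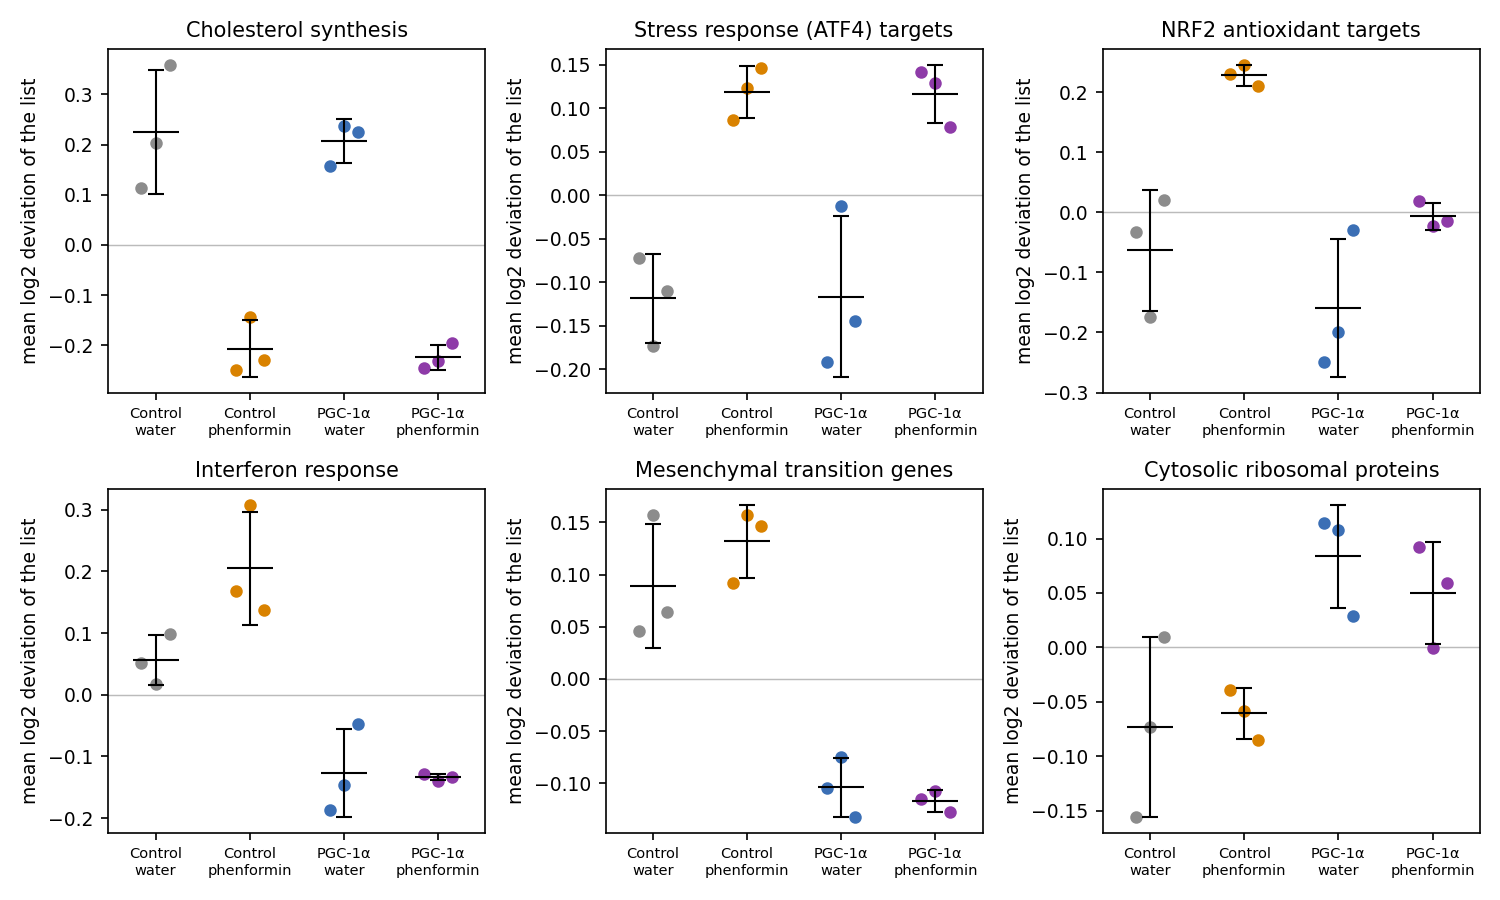
Mean log2 deviation of a gene list's members from each gene's mean over the 12 arrays (vertical axis), by group (horizontal axis), with 1 point per array and a bar at the group mean with its SD (n = 3). The cholesterol score lay at 0.23 and 0.21 in the water groups of the control and PGC-1alpha lines and at -0.21 and -0.22 in their phenformin groups, and the mesenchymal score was lower in the PGC-1alpha arrays of both treatments.

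Lists in which a smaller part of the members passed also shifted down in PGC-1alpha explants under phenformin. Of 29 NF-kB targets and chemokines 6 were lower and none higher, including the chemokines Ccl7 (at least 1.75-fold, -1.29 ± 0.13), Cxcl5 (1.55-fold) and Ccl2 (1.43-fold), with a list median of -0.14 (camera adjusted p = 0.00551, and adjusted p = 0.443 with an estimated correlation). Of the glycolysis genes 4 were lower, Slc2a1 by 1.57-fold, Pfkm by 1.53-fold, Pfkp by 1.36-fold and Aldoc by at least 1.30-fold, with a median of -0.13 (adjusted p = 0.0161). Egln3 (1.52-fold) and P4ha1 (1.74-fold) were lower among the hypoxia targets (median -0.25, adjusted p = 0.000364), and H2-K1 (1.73-fold) and H2-D1 (1.55-fold) among antigen presentation genes (median -0.15, adjusted p = 0.0132). With an estimated correlation the adjusted p was 0.252 for each of those 3 lists. Of 18 unfolded protein response genes Dnajb11 (1.65-fold) and Sdf2l1 (1.48-fold) were lower (median -0.18, adjusted p = 0.000556, and adjusted p = 0.443 with an estimated correlation). Of the replication genes Cdc45 (1.54-fold), Chaf1b (1.42-fold) and Ccne1 (1.36-fold) were lower (median -0.24, adjusted p = 0.00118, and adjusted p = 0.585 with an estimated correlation and 0.0905 with fry). Among NRF2 targets Gstm1 (3.89-fold), the exporter Abcc1 (1.92-fold) and Gsta2 (-0.72 ± 0.18) were lower and Cbr1 (0.62 ± 0.15) was higher (median -0.10, adjusted p = 0.0381, and adjusted p = 0.556 with an estimated correlation). Whichever of the 6 arrays was left out, Cdc45, Chaf1b, Ccne1, Gsta2, Cbr1 and Pfkp no longer passed. Aldoc passed in 1 of those 6 fits, Slc2a1 and P4ha1 in 2, and Egln3, Sdf2l1 and Ccl2 in 3. The other genes named in this paragraph passed in all 6.

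Mitochondrial lists did not shift up under phenformin as a group. Complex I had a median difference of 0.04 (adjusted p = 0.632), with its members Ndufb4 (-0.45 ± 0.12) and Ndufb4b (-0.50 ± 0.11), related genes whose probe sets can share signal, lower. Fatty acid oxidation had a median of -0.08 (adjusted p = 0.0714), with Cpt1a, the carnitine palmitoyltransferase of the outer membrane, 1.48-fold lower. Gabpa, a factor that partners with PGC-1 proteins, was 1.53-fold lower. Of 24 mitochondrial import genes and chaperones, Trap1 was 1.45-fold lower and Timm8a1 1.32-fold higher, and of 76 mitochondrial ribosomal proteins, Mrpl39 was 1.44-fold lower and Mrpl15 1.43-fold higher. The ATP synthase subunit Atp5o (1.32-fold) and the antioxidant genes Sod1 and Txnrd2 (1.36-fold each) were lower. Whichever of the 6 arrays was left out, Timm8a1, Mrpl15, Ndufb4, Atp5o and Sod1 no longer passed, and Ndufb4b and Txnrd2 passed in 1 of those 6 fits each, Trap1 in 4, Mrpl39 in 5 and Cpt1a and Gabpa in all 6. Cytosolic ribosomal proteins had a median of 0.10 (camera adjusted p = 0.000299, and adjusted p = 0.556 with an estimated correlation and 0.091 with fry). Marker lists of fibroblasts (median 0.07), leukocytes (-0.09), endothelium (-0.01) and lung epithelium (0.05) did not pass. Cth was higher in PGC-1alpha explants (0.59 ± 0.11), and the cystine transporter Slc7a11 1.45-fold lower, and they passed in 5 and 1 of those fits.

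Among the single genes with the largest differences, Pmp22 was at least 4.31-fold lower (-3.54 ± 0.23), Grem1 at least 3.92-fold, Loxl3 at least 3.40-fold, Cyp1b1 at least 2.27-fold and Adgrg2 at least 2.16-fold (-3.54 ± 0.22). Sod3 was 6.06-fold lower, Ifitm3 5.86-fold and Aqp5 5.50-fold, while Ptpn7 (at least 1.80-fold) and Mxra8 (at least 1.28-fold) were lower too. The cadherin Cdh17 was 2.79-fold higher (1.48 ± 0.13), Mrc1 at least 2.06-fold and Csn3 at least 2.02-fold. Armcx3 (2.79 ± 0.23), Pate14 (2.76 ± 0.23), Tlcd4 (1.71 ± 0.17), Slc44a3 (1.53 ± 0.16), Cyp2c55 (1.27 ± 0.12) and Trpa1 (1.25 ± 0.19) were higher within the range of the negative controls, as was Epha5 (1.36 ± 0.15) without a fold that could be bounded.

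limma called 783 genes, with 167 higher and 616 lower in PGC-1alpha explants. Of 71 named genes past the threshold, 37 passed whichever array was left out. The count was 401, 404 and 461 without PGC-1alpha phenformin replicates 1, 2 and 3, and 346 and 461 without control-line phenformin replicates 2 and 3. The NF-kB list no longer passed without control-line phenformin replicate 3 (adjusted p = 0.0532), and the NRF2 list without PGC-1alpha phenformin replicates 2 or 3 or control-line phenformin replicate 1 (adjusted p of up to 0.0985), after quantile normalization or above the median level. The PGC-1alpha differences in water and in phenformin, which share no arrays, correlated with r = 0.56 across genes. The genes called in both numbered 66 upwards, against 1.06 for independent lists, and 227 downwards, against 8.43, and none was called in opposite directions.

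**Figure D3:**
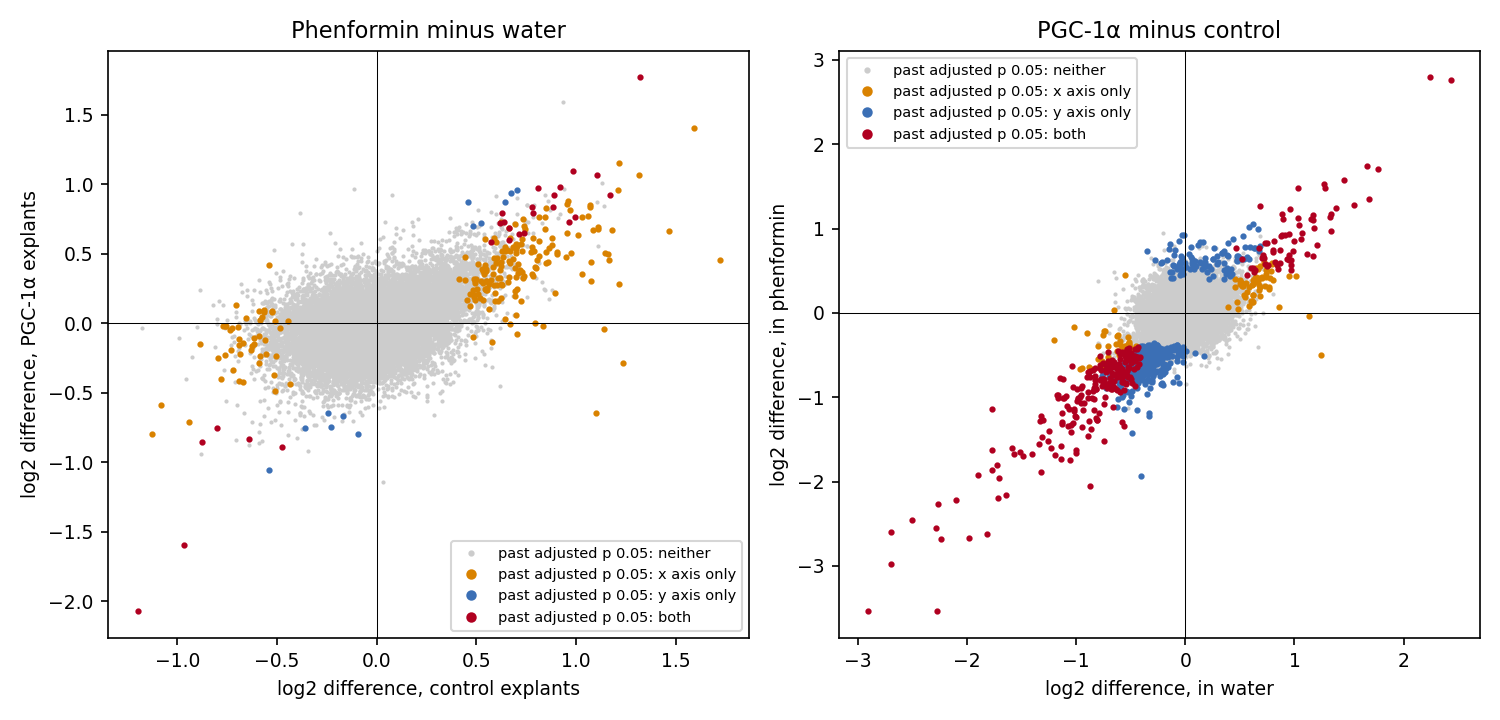
Log2 difference of each of the 19505 genes, 1 point per gene, with phenformin minus water on the left (control-line explants on the horizontal axis, PGC-1alpha explants on the vertical axis) and PGC-1alpha minus control-line on the right (in water on the horizontal axis, in phenformin on the vertical axis). Colours mark genes past an adjusted p of 0.05 on 1 axis, on both or on neither, with r = 0.46 on the left and r = 0.56 on the right.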

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

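The control gap as a covariate, the level-matched lists, the permutation of list scores, the number of lists in rebuilt data sets and the test of other cell types were chosen after results had been seen, and the tests of gene counts in rebuilt data sets, left-out arrays and other splits before theirs were.

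Differences between the lines in their phenformin response were found for 4 gene lists by camera with a preset correlation, each as a median of the PGC-1alpha response minus the control-line response. DNA replication genes gave -0.168, with -0.21 in PGC-1alpha and -0.04 in control-line explants, and 21 of 24 members were negative. Unfolded protein response genes gave -0.142, with 0.11 against 0.22, and 17 of 18 members were negative. NF-kB targets and chemokines gave -0.194, with -0.04 against 0.14, and 21 of 29 members were negative. Complex I subunits gave -0.114, with 0.01 against 0.13, and 33 of 36 members were negative. The complex I score was -0.106 ± 0.113 (SD, n = 3) in control-line water, where the arrays stood at -0.149, -0.191 and 0.023. It was 0.027 in control-line phenformin, 0.035 in PGC-1alpha water and 0.044 in PGC-1alpha phenformin. The complex I shifts for PGC-1alpha in water, for phenformin in control-line explants and for this difference all rest on the control-line water group, so they are not separate results. With an estimated correlation none of the 4 passed (adjusted p = 0.70 each). In 33 of 100 data sets rebuilt from equal responses with permuted residuals, the real one included, 4 or more lists passed, with 11 as the highest of the others, so equal responses may give this number of lists.

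The negative control probe sets, which belong to no comparison, were brighter by 0.231 in phenformin than in water (exact permutation of treatment within lines, two-sided p = 0.005, the smallest that 400 assignments can give). The rise was 0.29 in control-line and 0.17 in PGC-1alpha explants. The gap between positive and negative controls was 4.21 ± 0.07 (SD, n = 6) in water and 4.02 ± 0.06 (SD, n = 6) in phenformin, without overlap (exact permutation p = 0.005). The positive controls themselves differed by 0.04 (exact permutation p = 0.4).

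The first pattern weighed is the downward shift of the cholesterol synthesis list with phenformin in both lines. The list score fell by 0.43 ± 0.04 (SE) over both lines. With the control gap as a covariate the shift was -0.378 ± 0.096 (SE), still more than 2 SE below 0, which argues against the lower signal over background as its whole cause. The gap did not overlap between treatments, so this adjustment rests on how the score follows the gap within groups. Its mean lay at percentile 0 of 10000 random lists matched on level, whose lowest mean was -0.13, which argues against a trend with level, and treatment permuted within lines gave an exact permutation p = 0.005, which argues against the array-to-array spread. A response to the treatment that the design names stays open, and it may be a hypothesis to follow up, since the list was tested on the data in which its fall was seen.

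The second pattern is the larger number of genes called for phenformin in control-line than in PGC-1alpha explants, 234 against 38. In 20 of 100 data sets, the real one included, rebuilt from equal responses with permuted residuals, the ratio of counts (each plus 1, larger over smaller) was as large as the observed 6.03, and the highest of the others was 27.7. Equal responses in both lines may therefore give such counts. Single arrays moved both counts: the control-line count was 40 and 601 without its water replicates 2 and 3 and 96, 21 and 46 without its phenformin replicates 1, 2 and 3, and the PGC-1alpha count 14, 12 and 77 without its water and 3, 5 and 11 without its phenformin replicates 1, 2 and 3. With array weights the order turned, with 182 genes in control-line and 409 in PGC-1alpha explants. With only both groups fitted the counts were 13 and 15. The larger control-line count therefore depended on the fit. A difference between the lines stays open, and no gene passed its test.

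The third pattern is the lower interferon and mesenchymal lists in PGC-1alpha explants under phenformin. The mean score of fibroblast, leukocyte and endothelial markers differed by 0.021 ± 0.07 (SE), against an interferon shift of -0.34 ± 0.05 (SE), but 4 of 52 markers, 2 of 25 interferon and 12 of 21 mesenchymal genes exceeded the negative controls in all arrays of a group, so RNA of such cells carried over in control-line explants is not excluded. The 4 markers went both ways (log2 means), with Cd14 at 11.19 in control-line and 10.77 in PGC-1alpha explants, Flt1 at 9.84 and 9.37, Esam at 8.13 and 8.37 and Mrc1 at 7.48 and 8.96. The mean of both list scores was -0.29 ± 0.03 (SE), and -0.284 ± 0.026 (SE) with the control gap as a covariate. The gap overlapped between these groups, from 3.92 to 4.08 in PGC-1alpha and from 4.00 to 4.07 in control-line phenformin arrays. The adjustment could therefore move the shift little, so it does not decide about signal over background. An effect of the overexpressed coactivator, a difference between the explanted metastases that was fixed before treatment, and RNA of other cells stay open. So does a difference in signal over background that the gap does not show. The effect of the coactivator is the untested biological explanation that the design gives.

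Other splits of the same 6 arrays, with the other 6 kept in place, number 10 for 3 against 3, too few for a share under 0.05. The real split gave 391 genes for PGC-1alpha in water, 234 for phenformin in control-line, 38 for phenformin in PGC-1alpha and 783 for PGC-1alpha in phenformin explants. As many came from 1 of the 10 splits each, and the highest of the others gave 0, 1, 0 and 0 genes. For lists the real splits gave 9, 15, 5 and 10, and as many lists came from 2, 1, 4 and 1 of the 10 splits, with 9, 9, 6 and 5 as the highest of the others. For the difference of responses, with 0 genes, all 100 drawn splits gave as many. The highest of the others gave 334, in a split that moved 1 array of each line in water and all 3 in phenformin. As many as the 4 lists came from 47 of these splits, with 11 as the highest of the others. Such splits mix the difference between the lines into this contrast by construction, so they do not decide about chance.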

How the results depend on the processing

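No named gene that passed changed its sign under the alternatives run for it. The control gap as a covariate was chosen after seeing the data. Since the gap separates the treatments, its loss of phenformin calls cannot tell a technical shift from a treatment response that the covariate absorbs. The second value table was not run because its columns match no sample. The cause of the other moves was not tested, except that fits with fewer samples or genes differ by construction. The fit gave each gene 1 spread for all 4 groups. The median SD over genes was 0.196 in control-line water and 0.13 in control-line phenformin arrays. It was 0.148 in PGC-1alpha water and 0.121 in PGC-1alpha phenformin arrays. Errors of differences that use the control-line water arrays may therefore be too small. Array weights let the spread differ between arrays. With them the counts for PGC-1alpha in water and for phenformin in control-line explants fell from 391 to 305 and from 234 to 182. Both use the control-line water arrays. Those for phenformin in PGC-1alpha explants and for PGC-1alpha in phenformin, which do not, rose from 38 to 409 and from 783 to 1624. Fitting only both groups, with fewer arrays, gave 140, 13, 15 and 1032 in that order. The counts thus moved with how the spread was pooled, but unequal spread was not tested alone. Signal over background limits what can be said of genes inside the range of the negative controls, which were 117 of the 391, 69 of the 234, 9 of the 38 and 232 of the 783 calls.

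For PGC-1alpha in water, 391 genes became 626 with the trended and robust prior, 140 with only both groups fitted, 189 with the control gap, and 247 to 330 with an array left out. For phenformin in control-line explants, 234 became 666 with that prior, 637 above the median level, 13 with only both groups fitted, 0 with the control gap, and 21 to 601 with an array left out. For phenformin in PGC-1alpha explants, 38 became 250 with that prior, 409 with array weights, 62 after quantile normalization, 187 above the median level, 15 with only both groups fitted, 1 with the control gap, and 3 to 77 with an array left out. The difference of responses went from 0 to 3 with that prior and from 0 to 1 with an array left out. For PGC-1alpha in phenformin, 783 became 1624 with array weights, 1032 with only both groups fitted, and 346 to 584 with an array left out.

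Replicate numbers gave residual correlations of same-numbered arrays from -0.37 to 0.06, and not every array correlated best with its own number, so they do not pair the arrays. With the replicate number as a block the counts were 280, 100, 10, 0 and 555 for the 5 comparisons in that order of the text above. The agreements stayed at 0.462 and 0.557 by construction, since each number occurs once per group and the block leaves the differences unchanged.

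Lists that passed numbered 9 for PGC-1alpha in water, 15 and 5 for phenformin in control-line and PGC-1alpha explants, 4 for the difference and 10 for PGC-1alpha in phenformin. With an estimated correlation they numbered 0, 0, 0, 0 and 2. For phenformin in control-line explants 5 passed above the median level and 6 after quantile normalization. There the mitotic list was lost, with a median of 0.002 (camera adjusted p = 0.987), and only the direction that camera gave it turned. For the difference 0 passed with fry, 0 above the median level and 2 after quantile normalization. With an array left out the ranges were 5 to 11, 4 to 11, 3 to 6, 0 to 9 and 9 to 11. Above the median level the agreement of the phenformin responses rose from 0.462 to 0.658 and that of the PGC-1alpha responses from 0.557 to 0.745. With an array left out they ranged from 0.366 to 0.504 and from 0.40 to 0.578. Over the alternatives run for lists, the cholesterol and ATF4 lists passed in both lines under each but the estimated correlation. Of the named genes past the threshold, 26 of 40, 8 of 34, 3 of 22 and 37 of 71 passed under each alternative run for single genes (the block, quantile normalization, each array left out and, for genes above the median level, the filter on dim genes).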

Other observations

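All tests in this part were chosen after the data had been seen, as were the average effects and the gene groups, which were taken from the genes that led the average effect of phenformin.

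Averaged over both lines, 11 of 22 measured glutathione transferases rose with phenformin, none fell and 11 did not pass, with a median of 0.34. Gstm1 (1.19 ± 0.20), Gstm7 (0.93 ± 0.09), Gstm2 (0.86 ± 0.11), Gsta4 (0.70 ± 0.10) and Gstp1 (0.70 ± 0.11) were among them, and members of this family are near-identical, so that probe sets can share signal. Averaged over both treatments, 5 members were lower in PGC-1alpha explants and 1 was higher, with Gstm1 at -1.83, Gstm7 at -1.12 and Gstm2 at -1.02. Of 9 small heat shock proteins, which bind unfolding proteins, 4 rose with phenformin: Hspb6 (0.87 ± 0.18), Hspb1 (0.83 ± 0.12), Cryab (0.82 ± 0.12) and Hspb8 (0.44 ± 0.12). Gstm7, Gsta2 and Gsto2 (0.96 ± 0.12) lay inside the range of the negative controls in the 12 arrays.

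Of 16 Notch pathway genes, the ligands Dll4 (-1.64 ± 0.15) and Jag1 (-0.74 ± 0.10) and the target Hes1 (-0.28 ± 0.07) fell with phenformin, and none rose. The ligand Jag2 (-1.08, adjusted p = 2.26e-06) and the receptor Notch2 (-0.32, adjusted p = 0.0403) were lower in PGC-1alpha explants. Of 18 clock genes, Arntl (0.75 ± 0.11) and Dbp (0.69 ± 0.10) rose and Cry1 (-0.39 ± 0.08) fell with phenformin, while Dbp, Nr1d1, Bhlhe40, Tef and Rora were lower in PGC-1alpha explants. Txnip (-1.28 ± 0.12) and its relative Arrdc4 (-0.36 ± 0.09), both known to follow glucose metabolites, fell with phenformin. In PGC-1alpha explants Txnip was lower (-0.53) and Arrdc4 higher (0.60). Cry1, Tef, Rora and Arrdc4 lay inside the range of the negative controls in the 12 arrays.

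Per-array list scores were tested by exact permutation of treatment within lines and of line within treatments, two-sided, with 400 assignments and a smallest p of 0.005, adjusted over 36 lists. For phenformin 11 lists passed, 9 up and 2 down. Those down were cholesterol synthesis (-0.43) and fatty acid synthesis (-0.13). Among those up were ATF4 targets (0.24), NRF2 targets (0.22), tRNA synthetases (0.14), p53 targets (0.12) and lysosomal genes (0.09), each without overlap between treatments in either line. Complex II (0.11), glycolysis (0.09) and fatty acid oxidation genes (0.07) were up too, likewise without overlap. The median of the negative control probe sets rose by 0.231 with phenformin, with the same exact permutation p of 0.005. The lists that rose were not tested with the control gap as a covariate, so a technical shift is not excluded for them. For PGC-1alpha 8 lists passed, 2 up and 6 down. Cytosolic ribosomal proteins (0.13) and serine and one-carbon metabolism (0.07) were up, and interferon (-0.26), mesenchymal (-0.22), antigen presentation (-0.21), hypoxia (-0.20), glycolysis (-0.15) and fatty acid oxidation genes (-0.08) were down. Complex I did not pass for PGC-1alpha (0.08, exact permutation adjusted p = 0.201), nor did the PGC-1 family list (0.08, exact permutation adjusted p = 0.191). These permutations do not set a list against the other genes, as camera does. Complex II, with 4 genes, and serine and one-carbon metabolism passed camera in no comparison (smallest camera adjusted p of 0.575 and 0.284).

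Averaged over the lines, 894 genes passed for phenformin, 653 higher and 241 lower. Averaged over treatments, 1359 genes passed for PGC-1alpha against control-line explants, 360 higher and 999 lower. These averages use contrasts that are uncorrelated only where the 4 groups have equal spread. Here the median SD over genes ran from 0.121 in PGC-1alpha phenformin to 0.196 in control-line water arrays. A hypothesis is that the effects oppose each other, as in Pmp22, Adgrg2 and Cyp1b1, which were lower with PGC-1alpha and higher with phenformin. The genes up with phenformin and down with PGC-1alpha numbered 145, against 33.4 for independent lists, and those down and up 23, against 4.45. Those that moved the same way numbered 34 up, against 12.1, and 14 down, against 12.3. The correlation across genes was -0.20, and 12 of 100 splits with line labels permuted within treatments, the real one included, gave a value as low, with -0.38 as the lowest other, so an array structure that may give this value is not excluded.

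A second hypothesis is that PGC-1alpha explants respond less to phenformin. Over the 894 genes, the difference of responses signed by the average effect was -0.07 on average, against a mean effect size of 0.48, and 574 of the 894 were below 0. In 17 of 100 data sets rebuilt from equal responses, the real one included, the value was as low, with -0.15 as the lowest other, so a smaller response is not shown and may still exist.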
